A study of Mus musculus with 23 samples.

How the data were processed

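RNA was measured in 23 libraries of primary mouse astrocytes, the star-shaped glial cells of the brain. Per the labels' protocols, the cells came from the neocortex at postnatal day 3, grew for 7 days, and were stated to be over 95% astrocytes. They were kept for 24 h in 0.1% serum deprived of hormones before 10 nM T3 (triiodothyronine, the active thyroid hormone) was added. In the arm labelled CHX, 8 µg/ml of the compound was added 30 min before T3. CHX is read here as cycloheximide, an inhibitor of protein synthesis.

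Per the labels' protocols, libraries were made from 200 ng of RNA with a kit that does not mark strand, and single reads of 50 nt were sequenced. The submitters' processing notes name bcl2fastq, FastQC, Bowtie, TopHat, HTSeq, edgeR and the mouse genome build GRCm38, without versions. The counting mode, the strand setting and the annotation release are not given in the sources used here. Each deposited file holds raw counts of reads per Ensembl gene for 1 library, and these counts were used as deposited. Each file has 38293 genes and 5 closing lines that name no gene, which stayed out of library sizes and tests. Reads without a feature made up 3.75 to 5.81% of all lines' counts per library, ambiguous reads 1.40 to 1.71%, and alignments that were not unique 30.7 to 42.3%. Alignments that were not unique had not been counted to a gene, which lowers the counts of genes with near-identical copies. Since the kit marks no strand, reads of overlapping antisense genes cannot be told apart.

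Symbols and GRCm38 coordinates came from GENCODE release M21, in which 36345 of the identifiers were found, along with 504 of the 505 symbols in the gene lists. Libraries were grouped by their titles into 6 h control, 6 h T3, 6 h CHX, 6 h CHX plus T3 and 24 h control, with 4 libraries each, and 24 h T3 with 3. No label says that the replicates came from separate cultures or litters, so p-values measure the spread between these libraries, which may be technical. Gene counts per library ran from 13843040 to 22997873. All replicate pairs differed by more than sampling noise in a chi-square test over genes, and no pair of files was identical. File names carry a lane token. All 6 h control and 6 h T3 libraries were on lane 5, as were 6 h CHX replicates 1, 2 and 3. The other libraries were on lane 6, apart from 24 h T3 replicate 3 on lane 7.

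Tests were run with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups and its minimum count of 10, which left 16087 genes. Library sizes were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 23 libraries, with 17 residual degrees of freedom. The biological coefficient of variation was 8.57%. The quasi-likelihood F test was run for T3 at 6 h, T3 at 24 h, T3 with CHX, CHX alone, the difference of the T3 effect with and without CHX, and its difference between 24 h and 6 h. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with a standard error computed here as the size of the change divided by the square root of the F statistic. Levels are CPM (counts scaled to a common library size) on TMM-scaled library sizes, computed here from the deposited counts. Overlaps of calls stand beside the number that independent lists of the same sizes would share. The T3 comparisons at 6 h, at 24 h and with CHX share no library.

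The design, the tests, most alternatives, the rule for named genes and 21 gene lists were fixed before the data were examined. The lists cover thyroid hormone-responsive genes, thyroid hormone handling, astrocyte markers, reactive astrocyte genes, microglia, oligodendrocyte lineage, neuron, and vascular and meningeal markers, cell cycle, immediate early genes, ribosomal proteins, integrated stress, cholesterol, fatty acid synthesis, oxidative phosphorylation, extracellular matrix, retinoic acid, Notch, the circadian clock, interferon response and axon guidance. Each was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset to 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was repeated with the correlation estimated for each list, and fry was run as an alternative. The rule named, for the 4 main comparisons, the 10 genes per direction with the largest fitted change among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups, and for the differences of T3 effects 5 per direction without the overlap condition. It added the called members of both thyroid hormone lists, and Klf9, Hr, Dio3, Dio2 and Thrb in any case. From each list it added up to 4 members with the smallest adjusted p, called or not. Some genes that the rule names are not reported here. A list of motile cilia genes was added after the data had been seen, and so was the choice of the genes whose levels are printed.

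Alternatives were DESeq2 1.42.0, RLE factors in edgeR, no filter on low counts, a fit of only the groups compared, replicate numbers as a block, lane as a covariate, and each library left out in turn. Chosen after seeing the data were a fit with each library's trend on transcript length and GC content removed, known for 98.8% of the genes tested, and a fit without 24 h T3 replicate 1 and 6 h CHX replicate 4. The methods were tested on simulated counts with 200 changed genes. Simulated genes varied independently around a shared trend, without outlying libraries, so recovery in the real data may be lower. At a 2-fold change, with 67 genes changed, edgeR recovered 98.5% for T3 at 6 h (15817 genes tested) and 98.5% at 24 h (15823 genes). It recovered 97.0% with CHX (15824 genes) and 98.5% for CHX (15840 genes). For the differences of T3 effects it recovered 92.5% with CHX (15819 genes) and 97.0% between times (15825 genes). At a 1.5-fold change it recovered 83.6%, 76.1%, 88.1%, 86.6%, 61.2% and 62.7% in the same order, so smaller differences of T3 effects were often missed.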

Results

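The data describe how cultured mouse cortical astrocytes respond to T3, the active thyroid hormone, after 6 h and 24 h, and after 6 h in the presence of cycloheximide (CHX). Each condition had 4 libraries, except 24 h T3 with 3, and libraries held 13843040 to 22997873 gene counts. All tests of genes are edgeR quasi-likelihood F tests over 16087 genes. For T3 at 6 h, 9 of 35 splits of the same libraries, the real one included, gave as many lists called by camera, so a list's p at the preset correlation is weak evidence beside that with an estimated correlation. The kit marked no strand, and genes on the other strand overlap exons of Ccnd2, Ddit3, Dll1, Glul, Hes5, Nkx1-2, Nrarp, Thra, Ccna2, Atf5, Cox5a, Dbp, Galnt14, Loxl2, Nid1, Stat5a, Syt12, Ucp2, Fgfr3 and Bhlhe40, such as Nr1d1 for Thra and Stat3 for Stat5a. How reads of such overlaps were counted is not given in the sources used here.

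The first comparison asked which genes respond to T3 within 6 h. The gene raised most among those named was Hr, the Hairless corepressor (ENSMUSG00000022096, GRCm38 chromosome 14, 70552212 to 70573548), from 10.8 ± 1.32 CPM (SD, n = 4) in controls to 205 ± 14.7 CPM (SD, n = 4) with T3, a log2 fold change of 4.26 ± 0.08 (SE, adjusted p = 3.4e-22). Dio3, the deiodinase that inactivates T3 (ENSMUSG00000075707, GRCm38 chromosome 12, 110279068 to 110281097), rose by 3.60 ± 0.43 log2 from a control level of 0.143 ± 0.0324 CPM (SD, n = 4). Klf9, a zinc finger transcription factor (ENSMUSG00000033863, GRCm38 chromosome 19, 23141226 to 23168134), rose from 22.9 ± 1.92 CPM (SD, n = 4) to 79.6 ± 5.22 CPM (SD, n = 4), by 1.79 ± 0.09 log2. Ky and the myosin kinase gene Mylk2, which are known from muscle, rose by 2.92 ± 0.18 and 2.08 ± 0.20 log2.

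Other genes raised at 6 h were the sulfotransferase gene Chst8 (1.96 ± 0.29 log2), the prolactin receptor gene Prlr (1.76 ± 0.32), the retinoid isomerase gene Rpe65 (1.73 ± 0.25), Syt12 (1.69 ± 0.15), the aggrecanase gene Adamts5 (1.56 ± 0.13) and the signalling factor gene Stat5a (1.41 ± 0.10). Among the lowered genes were the muscarinic receptor gene Chrm4 (−1.03 ± 0.19 log2), the meiotic cohesin gene Rec8 (−0.95 ± 0.20), the Wnt receptor gene Fzd9 (−0.79 ± 0.14) and the tendon factor gene Scx (−0.66 ± 0.14). In all, 606 genes were called, 420 higher and 186 lower, of which 46 and 7 changed at least 2-fold. The count was 387 without 6 h control replicate 2, 349 without 6 h T3 replicate 4, 1226 with the length and GC trend removed, and 1191 without 24 h T3 replicate 1 and 6 h CHX replicate 4, which only add to the shared estimate of the spread.

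**Figure D1:**
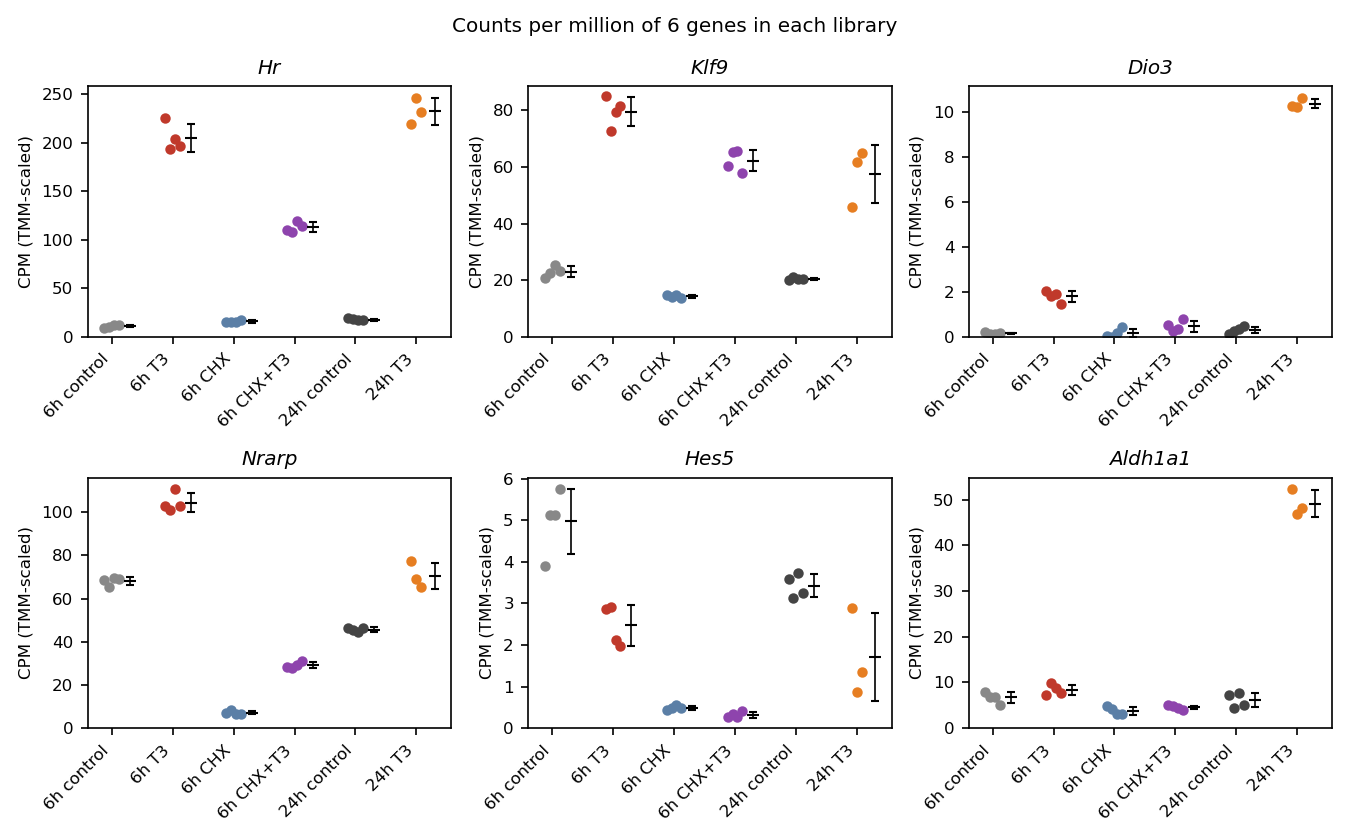
CPM (TMM-scaled, linear axes from 0) of Hr, Klf9, Dio3, Nrarp, Hes5 and Aldh1a1 in the 23 libraries, with 1 point per library and the mean and SD of each group in black. Hr lies at 10.8 CPM in the 6 h controls and 205 CPM with T3, and Aldh1a1 reaches 49.2 CPM in the 24 h T3 libraries against 6.11 CPM in their controls.

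Of 24 thyroid hormone-responsive genes tested, 10 rose at 6 h over all genes, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.2e-11, and adjusted p = 1.1e-05 with an estimated correlation). They included the potassium channel gene Kcnj10 (0.52 ± 0.08 log2), the semaphorin gene Sema7a (0.64 ± 0.11), the clock output factor gene Dbp (0.51 ± 0.10) and Gbp3 (0.79 ± 0.11). Of 19 handling genes 2 rose over all genes, Dio3 and the receptor gene Thrb, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.372). Thrb had a log2 fold change of 0.51 ± 0.12 (adjusted p = 0.0119, and 0.0628 without 6 h T3 replicate 1). The activating deiodinase gene Dio2 did not pass the test (−0.22 ± 0.09 log2, adjusted p = 0.188).

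Genes of the Notch pathway, which acts between neighbouring cells, moved in both directions at 6 h. Nrarp (0.61 ± 0.06 log2) and Hey1 (0.41 ± 0.06) rose. The effector gene Hes5 fell from 4.98 ± 0.778 CPM (SD, n = 4) to 2.48 ± 0.491 CPM (SD, n = 4) and Hes1 had a log2 fold change of −0.43 ± 0.09. Over all genes 2 of 16 members rose and 3 fell, and 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0419, and adjusted p = 0.271 with an estimated correlation). Over all genes 6 fell with the length and GC trend removed. Of 30 cell cycle genes 7 fell over all genes and 16 adjusted over the list alone (camera adjusted p = 2.7e-10, and adjusted p = 0.271 with an estimated correlation). Over all genes 16 fell with the length and GC trend removed, 11 with lane as a covariate and 14 without 24 h T3 replicate 1 and 6 h CHX replicate 4. All libraries of this comparison were on lane 5, so the lane term changed only the shared estimate of the spread. Of the cell cycle genes, Ccnb2 had a log2 fold change of −0.47 ± 0.11 (adjusted p = 0.0166). That p was 0.0537 without 6 h control replicate 2 and 0.06965 without 6 h T3 replicate 1.

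Of 22 astrocyte markers 3 rose and 1 fell at 6 h over all genes, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0842). Over all genes 6 rose with the length and GC trend removed. The sodium pump subunit gene Atp1b2 rose by 0.59 ± 0.07 log2 and the growth factor receptor gene Fgfr3 fell by 0.28 ± 0.06. Of 15 fatty acid genes 2 rose and 1 fell over all genes, with the elongase gene Elovl5 at 0.33 ± 0.05 log2, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.12). Of 25 cholesterol genes 1 rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00387, and adjusted p = 0.618 with an estimated correlation). Of 18 clock genes Bhlhe40 and Dbp rose over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00588, and adjusted p = 0.449 with an estimated correlation).

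Markers of other cells were measured beside these genes at 6 h. Of 13 neuron markers 1 rose over all genes, Elavl4 (0.63 ± 0.13 log2), and 4 adjusted over the list alone (camera adjusted p = 0.00736, and adjusted p = 0.618 with an estimated correlation), while 3 rose over all genes with lane as a covariate. The median log2 fold change was 0.14 for 16 microglia markers (camera adjusted p = 0.143) and 0.21 for 10 oligodendrocyte lineage markers (camera adjusted p = 0.536). The 14 vascular and meningeal markers had a median of −0.03 and a mean of −0.05 log2, while their test pointed upward (camera adjusted p = 0.922). In a list chosen after the data had been seen, all 34 motile cilia genes had positive values, with a median of 0.66 log2, and 9 were called. The count was 19 with the length and GC trend removed, 17 with lane as a covariate and 21 without 24 h T3 replicate 1 and 6 h CHX replicate 4. The 6 h control and 6 h T3 libraries were all on lane 5, so a lane effect was not tested here. For these genes and the neuron markers the lane term changed only the shared estimate of the spread, and the cilia median stayed at 0.66.

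The second comparison asked which genes differ after 24 h of T3. Dio3 changed most among the named genes, from 0.293 ± 0.137 CPM (SD, n = 4) to 10.4 ± 0.216 CPM (SD, n = 3), by 5.10 ± 0.31 log2. Hr was still raised, at 233 ± 13.9 CPM (SD, n = 3) against 17.6 ± 1.03 CPM (SD, n = 4), by 3.73 ± 0.08 log2 (adjusted p = 4.1e-21). Aldh1a1, a retinaldehyde dehydrogenase gene (ENSMUSG00000053279, GRCm38 chromosome 19, 20492715 to 20643465), rose from 6.11 ± 1.58 CPM (SD, n = 4) to 49.2 ± 2.87 CPM (SD, n = 3), by 3.01 ± 0.15 log2. Its neighbour Aldh1a7 rose by 3.27 ± 0.16 log2. How similar their sequences are was not tested, and reads that align to both genes would have been left uncounted.

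Also raised at 24 h were Chst8 (2.97 ± 0.28 log2), Galnt14 (2.96 ± 0.25), Rpe65 (2.94 ± 0.20), Prlr (2.39 ± 0.31), Adamts17 (2.37 ± 0.16), Syt12 (2.31 ± 0.15) and Stat5a (1.63 ± 0.10). Klf9 was 2.83-fold higher, at 57.6 ± 10.3 CPM (SD, n = 3) against 20.4 ± 0.375 CPM (SD, n = 4). Among the lowered genes were Nptx1, which encodes a neuronal pentraxin (−1.25 ± 0.19 log2), Chrm4 (−1.25 ± 0.18), Fzd9 (−1.11 ± 0.16), Stk32b (−1.11 ± 0.25) and Mpped1 (−1.10 ± 0.16). In all, 1140 genes were called, 709 higher and 431 lower, of which 99 and 22 changed at least 2-fold. The count was 401 when only the 24 h libraries were fitted, in which Mcm2 (adjusted p = 0.078) and Cox5a (0.104) were not called, and 1795 with the length and GC trend removed.

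At 24 h 14 of the 24 thyroid hormone-responsive genes rose over all genes, and 15 rose and 4 fell adjusted over the list alone (camera adjusted p = 1.4e-12, and adjusted p = 5.0e-06 with an estimated correlation). Dbp rose by 0.80 ± 0.10 log2, Gbp3 by 1.11 ± 0.11 and the mitochondrial carrier gene Ucp2 by 0.55 ± 0.11. Of 19 handling genes 3 rose and 1 fell over all genes, and 3 rose and 2 fell adjusted over the list alone. The transporter gene Slco1a4 rose by 0.85 ± 0.08 log2 and Slc7a5, another transporter gene, fell by 0.35 ± 0.07. The median of this list was −0.12 and its mean 0.23 log2, and its test pointed downward (camera adjusted p = 0.784).

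Of 13 retinoic acid genes Aldh1a1 and the binding protein gene Crabp1 (1.61 ± 0.19 log2) rose at 24 h over all genes, and 4 rose and 2 fell adjusted over the list alone. The median of this list was −0.22 and its mean 0.08 log2, and its test pointed upward (camera adjusted p = 0.395). Of 16 Notch genes 2 rose and 8 fell over all genes, with the same counts adjusted over the list alone (camera adjusted p = 0.00362, and adjusted p = 0.0687 with an estimated correlation). Nrarp rose by 0.63 ± 0.06 log2 and Heyl fell by 1.41 ± 0.31. Of 22 astrocyte markers 5 rose and 3 fell over all genes, with 6 and 3 adjusted over the list alone. Atp1b2 rose by 0.85 ± 0.07 log2 and the lipid enzyme gene Acsbg1 by 0.55 ± 0.06. The markers' median was −0.03 and their mean 0.03 log2, and the test pointed upward (camera adjusted p = 0.395). Of 35 extracellular matrix genes 3 rose and 7 fell over all genes, and 3 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.0536). The collagen gene Col8a1 rose by 1.14 ± 0.13 log2 and the crosslinking enzyme gene Loxl2 by 0.98 ± 0.09, while the laminin gene Lama4 fell by 0.81 ± 0.13 and the nidogen gene Nid1 by 0.76 ± 0.11.

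Markers of other cells had negative medians at 24 h. The median was −0.42 log2 for 14 vascular and meningeal markers (camera adjusted p = 0.354), of which 2 rose and 1 fell over all genes, and 2 rose and 3 fell adjusted over the list alone. It was −0.45 for 10 oligodendrocyte lineage markers (camera adjusted p = 0.0536, and 0.0363 without 24 h T3 replicate 1), of which 2 fell over all genes and 3 adjusted over the list alone. For 16 microglia markers it was −0.26 (camera adjusted p = 0.064, and 0.032 without that library), and for 13 neuron markers −0.23 (camera adjusted p = 0.064). Without that library 1 vascular and meningeal marker rose, the lower call in that list was lost, and 1 oligodendrocyte lineage marker fell over all genes. The oligodendrocyte lineage mean was 5.66 and 5.77 log2 CPM in 24 h control replicates 2 and 4. It was 4.65 and 4.45 in control replicates 1 and 3, and 4.68 to 4.91 with T3. The means of the other lists named here were also highest in control replicates 2 and 4, so the negative medians rest largely on those controls.

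All 38 oxidative phosphorylation genes, which encode parts of the respiratory chain and ATP synthase, had positive values at 24 h, with a median of 0.32 log2. Of these 10 rose over all genes and 34 adjusted over the list alone, with Cox5a at 0.55 ± 0.12 log2 (camera adjusted p = 4.4e-12, and adjusted p = 0.449 with an estimated correlation). Without 24 h T3 replicate 1, in which 42.3% of the lines' counts were alignments that were not unique against 37.5 and 37.3% in replicates 2 and 3, the median was 0.12 and 2 members were called. The count was 19 with the length and GC trend removed and 26 with lane as a covariate. With lane the 24 h T3 effect rests on T3 replicates 1 and 2, since T3 replicate 3 alone was on lane 7. Replicate 1 thereby gains weight, and the median with lane was 0.42. The 48 ribosomal protein genes had a median of 0.15 log2 (camera adjusted p = 0.0217, and adjusted p = 0.757 with an estimated correlation), and of 0.03 with the length and GC trend removed. Without 24 h T3 replicate 1 their median was −0.11 log2 and their test pointed downward (camera adjusted p = 0.032). After T3 at 6 h the median was −0.12 log2 for oxidative phosphorylation, with 2 of 38 values positive (camera adjusted p = 5.2e-04, and adjusted p = 0.797 with an estimated correlation), and −0.13 for ribosomal proteins, with 4 of 48 positive (camera adjusted p = 0.00387, and adjusted p = 0.797 with an estimated correlation).

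Of 30 cell cycle genes 8 fell at 24 h over all genes and 16 adjusted over the list alone, with the replication gene Mcm2 at −0.29 ± 0.06 log2 (camera adjusted p = 2.1e-10, and adjusted p = 0.2 with an estimated correlation). Over all genes 14 fell with the length and GC trend removed and 16 without 24 h T3 replicate 1 and 6 h CHX replicate 4. Of 31 immediate early genes 5 fell over all genes, and 2 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.00372, and adjusted p = 0.501 with an estimated correlation). Btg2 fell by 0.56 ± 0.08 log2 and Nr4a3 by 0.66 ± 0.14. Of 20 reactive astrocyte genes 2 fell over all genes, and 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 2.6e-04, and adjusted p = 0.449 with an estimated correlation). Without 24 h T3 replicate 1, 4 of them fell over all genes. Their mean log2 CPM was 5.67 and 5.66 in 24 h control replicates 2 and 4. It was 5.04 and 5.00 in control replicates 1 and 3, and 5.00 to 5.17 with T3, so this fall rests largely on control replicates 2 and 4. Of 38 axon guidance genes 4 rose and 2 fell over all genes, and 5 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.74, and 0.0136 without 24 h T3 replicate 1). The changes were −0.73 ± 0.13 log2 for Slit1 and 0.57 ± 0.11 for the netrin receptor gene Unc5b. Of 20 integrated stress genes 3 rose and 2 fell over all genes, and 3 rose and 4 fell adjusted over the list alone. The change of Atf5 was 0.52 ± 0.08 log2. The list's median was 0.00 and its mean −0.01 log2, and its test pointed downward (camera adjusted p = 0.752).

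**Figure D2:**
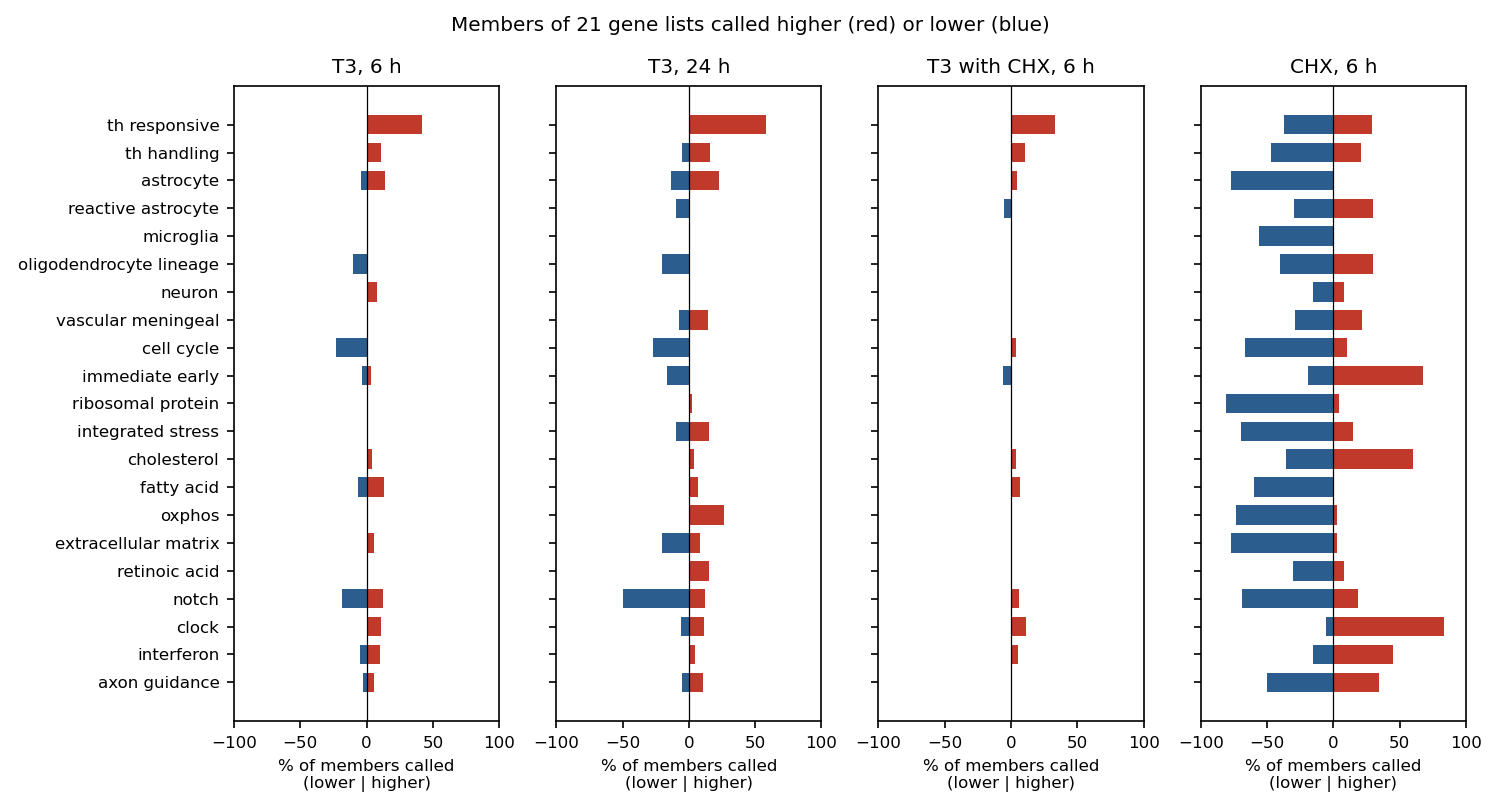
Percent of the tested members of each of 21 gene lists called higher (red, right of 0) or lower (blue, left of 0) in the 4 main comparisons, with the adjusted p taken over all 16087 genes. The thyroid hormone-responsive list has 10, 14 and 8 of 24 members higher with T3 at 6 h, at 24 h and with CHX. CHX alone, which called 67.5% of all tested genes, changed members of each list.

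Of the 420 genes higher at 6 h, 214 were also called higher at 24 h, where independent lists would share 18.5, and of the 186 lower ones 63 were lower again, where independent lists would share 4.98. The test of the difference between times called 135 genes, 87 with a higher and 48 with a lower value at 24 h. Aldh1a7 (2.95 ± 0.24 log2), Aldh1a1 (2.70 ± 0.22), Adamts16 (1.96 ± 0.36), Adamts17 (1.90 ± 0.29) and Crabp1 (1.90 ± 0.27) had higher values at 24 h, and the ubiquitin ligase gene March4 (−1.34 ± 0.18) and Nptx1 (−1.33 ± 0.24) lower ones. Time coincided with the sequencing lane, though each T3 effect was taken within a time. Among the 24 h libraries T3 replicate 3 alone was on lane 7. With lane as a covariate the 24 h T3 effect therefore rests on T3 replicates 1 and 2. The count was 521 with lane as a covariate, 410 with the length and GC trend removed, 365 with DESeq2 and 62 in a fit of only these groups. It was 69, 247 and 74 without 24 h control replicates 2, 3 and 4, and 350 without 24 h T3 replicate 3. Without a 6 h library it was 80 and 75 without control replicates 1 and 2, and 74, 82 and 75 without T3 replicates 1, 3 and 4.

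The third comparison, T3 in the presence of CHX, asked which responses are seen while protein synthesis is inhibited. Hr went from 15.7 ± 1.16 CPM (SD, n = 4) to 113 ± 5.39 CPM (SD, n = 4), by 2.85 ± 0.07 log2, and Klf9 from 14.3 ± 0.558 CPM (SD, n = 4) to 62.3 ± 3.71 CPM (SD, n = 4), by 2.12 ± 0.09 log2. Nrarp, a feedback regulator of Notch (ENSMUSG00000078202, GRCm38 chromosome 2, 25180758 to 25183339), rose from 7.18 ± 0.713 CPM (SD, n = 4) to 29.1 ± 1.41 CPM (SD, n = 4), by 2.02 ± 0.07 log2. Ky was 5.66-fold and the collagen-processing gene Pcolce2 2.82-fold higher. Dio3 did not pass the test, at 0.461 ± 0.234 CPM (SD, n = 4) against 0.163 ± 0.193 CPM (SD, n = 4) (adjusted p = 0.203).

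With CHX, T3 also raised the receptor gene Gper1 (1.24 ± 0.13 log2), Stat5a (1.15 ± 0.10) and Angptl2 (1.13 ± 0.11), and lowered Rassf6 (−0.80 ± 0.15) and the kinase gene Pim2 (−0.45 ± 0.08). In all 208 genes were called, 187 higher and 21 lower. The CHX plus T3 libraries and 6 h CHX replicate 4 were on lane 6 and the other CHX libraries on lane 5. With lane as a covariate, where the comparison rests on that replicate alone, 660 genes were called, 326 higher and 334 lower. The count was 388 with the length and GC trend removed, 343 with DESeq2, 407 in a fit of only these groups, and 138 without 6 h CHX plus T3 replicate 3.

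With CHX 8 of 24 thyroid hormone-responsive genes rose with T3 over all genes and 11 adjusted over the list alone, with Kcnj10 at 0.46 ± 0.08 log2 (camera adjusted p = 2.1e-11, and adjusted p = 9.8e-06 with an estimated correlation). Of 18 clock genes 2 rose over all genes and 8 adjusted over the list alone, with Bhlhe40 at 0.37 ± 0.05 log2 (camera adjusted p = 1.5e-07, and adjusted p = 0.049 with an estimated correlation, which was 0.0689 without 6 h CHX replicate 4). Of 30 cell cycle genes 1 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 6.8e-09, and adjusted p = 0.168 with an estimated correlation). The former was Cenpf (0.48 ± 0.10 log2), with an adjusted p of 0.0857 without 6 h CHX replicate 4 and 0.092 without 6 h CHX plus T3 replicate 3. The median of the cell cycle list was 0.16 log2, and 0.09 without 6 h CHX replicate 4. With lane as a covariate, which rests on that replicate alone, it was 0.46. With the length and GC trend removed 5 members rose over all genes. The 13 neuron markers had a median of −0.43 log2 (camera adjusted p = 0.00177, and adjusted p = 0.383 with an estimated correlation). Without 6 h CHX replicate 4 the median was −0.12 and the camera adjusted p 0.0846. That library had a mean log2 CPM of 3.35 over these markers, against 2.53 to 2.73 in the other CHX libraries.

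Other lists also had negative medians after T3 with CHX. For 16 microglia markers the median was −0.37 log2 (camera adjusted p = 1.9e-05, and adjusted p = 0.292 with an estimated correlation). Without 6 h CHX replicate 4 it was −0.26 and the camera adjusted p 7.6e-04. Of 20 reactive astrocyte genes, with a median of −0.23 log2, 1 fell over all genes and 5 adjusted over the list alone (camera adjusted p = 7.1e-05, and adjusted p = 0.292 with an estimated correlation). Without the same library their median was −0.17, the camera adjusted p was 0.00411 and the call over all genes was lost, while 4 fell with the length and GC trend removed and 6 with lane as a covariate. The median was −0.29 log2 for oligodendrocyte lineage markers (camera adjusted p = 0.0549) and −0.06 for vascular and meningeal markers (camera adjusted p = 0.958). Without 6 h CHX replicate 4 these medians were −0.145 and −0.09. With lane as a covariate, which rests on that replicate alone, they were −0.64 and 0.45.

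Of the 420 genes raised by T3 at 6 h, 124 were also called higher with CHX, where independent lists would share 4.88, and 74.0% had a positive value. Of the 186 lowered genes edgeR called 0 lower with CHX, where independent lists would share 0.243. Since only 21 genes were called lower with CHX, this count alone decides little. At an unadjusted p under 0.05, 7 of the 186 were lower with CHX, and DESeq2 also found 0 genes lower in both comparisons. Of the genes lowered at 6 h in other fits, 2 were lower in both with lane as a covariate, 4 with the length and GC trend removed, 3 without 24 h T3 replicate 1 and 6 h CHX replicate 4, and 1 in fits of only the groups compared. The median log2 fold change of the 186 genes was −0.34 without CHX, 0.01 with it and −0.21 at 24 h. In all, 100 genes were called higher in each of the T3 comparisons.

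**Figure D3:**
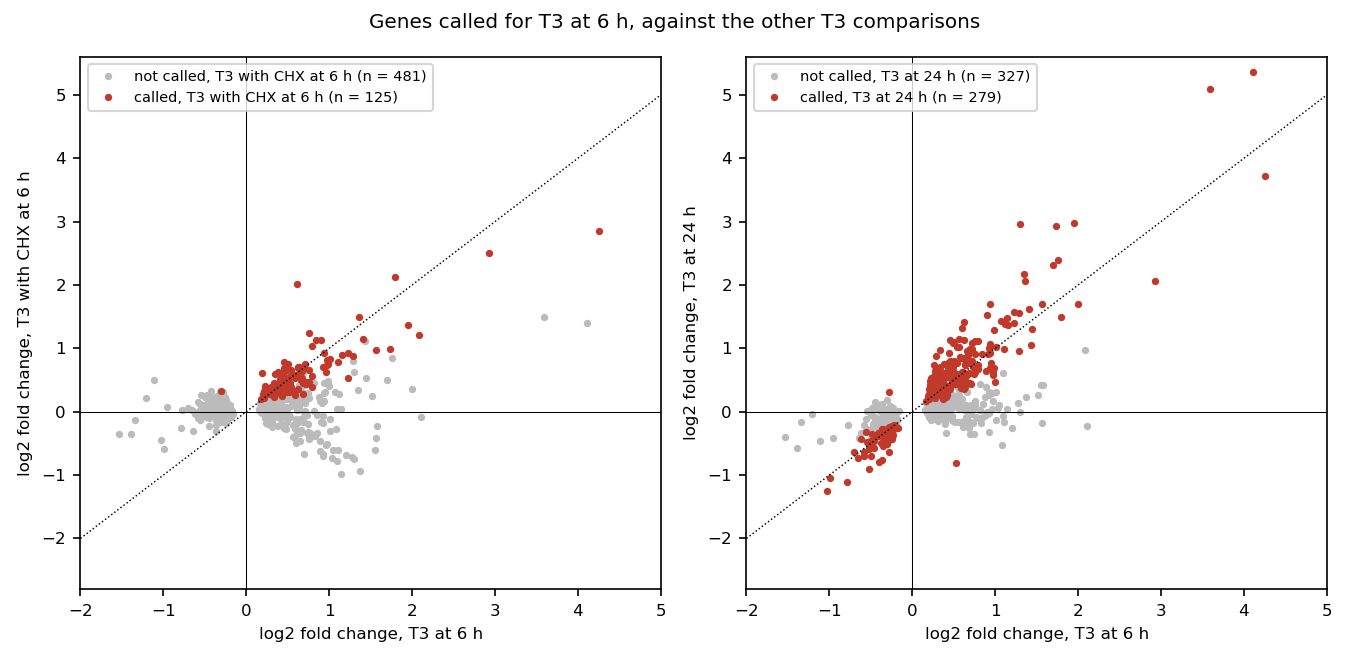
Log2 fold changes of the 606 genes called for T3 at 6 h (x axis) against T3 with CHX (left, y axis) and T3 at 24 h (right, y axis), with 1 point per gene, red where the second comparison also called the gene in either direction (125 and 279 genes), and a dotted line of equal values. Genes lowered at 6 h scatter around 0 with CHX (median 0.01) and lie mostly below 0 at 24 h (median −0.21).

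The difference of the T3 effect with and without CHX passed the test for 196 genes, 94 with a higher and 102 with a lower value in CHX. The value of Nrarp was higher with CHX by 1.40 ± 0.09 log2 (adjusted p = 9.7e-10), that of Klf13, a relative of Klf9, by 0.88 ± 0.12, that of Hes1 by 0.75 ± 0.13 and that of the cyclin gene Ccna2 by 0.57 ± 0.11. For Hr the difference was −1.41 ± 0.11 log2 (adjusted p = 1.4e-08). The larger ratio of Nrarp started from a lower level, 6.74 to 8.24 CPM with CHX against 65.4 to 69.6 CPM in the controls. With T3 it was at 27.99 to 31.05 CPM with CHX and at 101 to 111 CPM without, so its gain in CPM was smaller with CHX. Of the 420 raised genes 67 had a smaller or opposite effect with CHX, and of the 186 lowered ones 49, though these genes were chosen by the effect that is subtracted here, which favours such calls. Of 30 cell cycle genes 8 had a higher value with CHX over all genes and 23 adjusted over the list alone (camera adjusted p = 1.0e-19, and adjusted p = 0.0366 with an estimated correlation). Over all genes 2 members were called without 6 h CHX replicate 4, where the median was 0.30 log2 against 0.38 and 28 values were positive, and 11 without 24 h T3 replicate 1 as well. The count was 16 with the length and GC trend removed. With lane as a covariate, where the T3 effect with CHX rests on 6 h CHX replicate 4 alone, the median was 0.66. That library had a cell cycle mean of 5.27 log2 CPM, against 5.55 to 5.62 in the other CHX libraries. Of 16 Notch genes 2 had a higher value with CHX over all genes and 5 adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.00646 with an estimated correlation). The count over all genes was 6 with the length and GC trend removed. CHX alone lowered 11 of the 16.

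For this difference between T3 effects, the T3 effect with CHX rests on 6 h CHX replicate 4 alone when lane is a covariate. The count of 196 was 693 with the length and GC trend removed, 514 with DESeq2, 497 in a fit of only the 6 h groups and 295 without the low-count filter. It was 68, 30 and 42 without 6 h control replicates 1 to 3, and 93, 118, 46 and 30 without 6 h T3 replicates 1 to 4. Of the CHX arm, it was 334 and 47 without 6 h CHX replicates 3 and 4, and 77, 31, 34 and 89 without CHX plus T3 replicates 1 to 4.

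The fourth comparison measured CHX itself at 6 h without T3. CHX raised the homeobox genes Nkx1-2 (5.96 ± 0.45 log2) and Lhx4 (5.27 ± 0.37), the G protein regulator gene Rgs1 (5.59 ± 0.23), the peptide receptor gene Vipr1 (5.21 ± 0.39) and the chemokine gene Ccl20 (4.91 ± 0.33). It lowered Lzts1 (−4.53 ± 0.32 log2), the chaperone gene Hspa2 (−3.58 ± 0.11), Hes5 (−3.31 ± 0.27), Nrarp (−3.25 ± 0.07) and the cyclin gene Ccnd2 (−3.45 ± 0.10), the last from 788 ± 44.6 CPM (SD, n = 4) to 72 ± 3.2 CPM (SD, n = 4). The clock repressor gene Nr1d1 went from 60.6 ± 3.27 CPM (SD, n = 4) to 710 ± 33.6 CPM (SD, n = 4). In all 10862 genes, or 67.5% of those tested, were called, 5946 higher and 4916 lower, of which 1883 and 931 changed at least 2-fold. These are changes relative to other genes, and a change in total RNA per cell would not be seen. The counts of list members called with CHX are to be read beside that share of all genes.

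Of 31 immediate early genes 21 rose and 6 fell with CHX over all genes, with the same counts adjusted over the list alone (camera adjusted p = 1.1e-04, and adjusted p = 0.328 with an estimated correlation). Cxcl1 rose by 4.36 ± 0.12 log2, Gadd45b by 4.17 ± 0.09, Egr2 by 3.95 ± 0.15 and Atf3 by 3.78 ± 0.14. Of 18 clock genes 15 rose and 1 fell, again with the same counts adjusted over the list alone (camera adjusted p = 8.5e-05, and adjusted p = 0.195 with an estimated correlation). Ciart was at 3.01 ± 0.11 log2 and Per1 at 2.11 ± 0.06. Of 16 Notch genes 3 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.00609, and adjusted p = 0.195 with an estimated correlation). Lfng was at −3.21 ± 0.08 log2 and Dll1 at −1.31 ± 0.10.

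CHX lowered 39 of 48 ribosomal protein genes and raised 2, with the same counts adjusted over the list alone (camera adjusted p = 8.5e-05, and adjusted p = 0.587 with an estimated correlation). Of 22 astrocyte markers 17 fell over all genes and 17 adjusted over the list alone, with the glutamine synthetase gene Glul at −0.87 ± 0.04 log2 (camera adjusted p = 2.1e-04, and adjusted p = 0.21 with an estimated correlation). Of 35 extracellular matrix genes 27 fell and 1 rose, with the same counts adjusted over the list alone and Col8a1 at −1.59 ± 0.13 log2 (camera adjusted p = 1.1e-04, and adjusted p = 0.496 with an estimated correlation). Of 15 fatty acid genes 9 fell over all genes and 9 adjusted over the list alone, with the desaturase gene Scd2 at −1.38 ± 0.06 log2 (camera adjusted p = 0.00208, and adjusted p = 0.21 with an estimated correlation). Of 20 integrated stress genes 3 rose and 14 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00672, and adjusted p = 0.381 with an estimated correlation). The changes were 3.14 ± 0.07 log2 for the transcription factor gene Atf4, 3.04 ± 0.10 for Ddit3 and −1.71 ± 0.12 for the folate enzyme gene Mthfd2.

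CHX lowered 20 of 30 cell cycle genes and raised 3 (camera adjusted p = 0.00165, and adjusted p = 0.587 with an estimated correlation), and lowered 28 of 38 oxidative phosphorylation genes and raised 1 (camera adjusted p = 2.9e-04, and adjusted p = 0.587 with an estimated correlation), with the same counts adjusted over each list alone. Among markers of other cells, 9 of 16 microglia markers fell, also adjusted over the list alone, with a median of −0.52 log2 (camera adjusted p = 0.0326, and adjusted p = 0.587 with an estimated correlation). Of 10 oligodendrocyte lineage markers 3 rose and 4 fell (camera adjusted p = 0.185), of 14 vascular and meningeal markers 3 rose and 4 fell (camera adjusted p = 0.65), and of 13 neuron markers 1 rose and 2 fell (camera adjusted p = 0.65). Adjusted over the list alone 3 vascular and meningeal markers fell, and the other counts were the same. Without 6 h CHX replicate 4, 1 oligodendrocyte lineage marker rose and 6 fell over all genes, and 4 neuron markers fell.

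Other lists had members called in both directions with CHX, as would be common where 67.5% of all tested genes were called. Of 25 cholesterol genes 15 rose and 9 fell over all genes, and 16 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.418). Stard4 rose by 1.27 ± 0.10 log2 and Sqle fell by 2.07 ± 0.06. Of 20 interferon genes 9 rose and 3 fell, with the same counts adjusted over the list alone, with Mx2 at 3.08 ± 0.26 log2 (camera adjusted p = 0.281). Of 19 thyroid hormone handling genes 4 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.185). The receptor gene Thra fell by 0.72 ± 0.05 log2, while the transporter gene Slc7a8 rose by 2.49 ± 0.12.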

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

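Some tests were chosen only after the results were seen. These were the motile cilia list, its tests of a lower share of the main cell type and of more multiciliated cells, the test of 24 h T3 replicate 1, both tests of 6 h CHX replicate 4, and the fits with the length and GC trend removed and without those libraries.

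Motile cilia genes, which build the beating cilia of ependymal and other multiciliated cells, had higher values in the 6 h T3 libraries than in their controls, with a median of 0.66 log2 and 34 of 34 members positive. With the length and GC trend removed the median was 0.71 and 19 were called against 9, which speaks against that trend as the whole cause. The vascular and meningeal markers had a median of −0.0335, which speaks against a lower share of astrocytes that raises all other cells alike. Neuron, oligodendrocyte lineage and microglia markers had medians of 0.40, 0.21 and 0.14. A change in cell content that leaves out vascular and meningeal cells is therefore not excluded. In the test of more multiciliated cells, the 5 members with at least 20 CPM in the controls had a median of 0.36 (quartiles 0.26 to 0.54) and the other 29 a median of 0.80 (quartiles 0.58 to 0.94). As first written, the rule of this test read such values as evidence against more multiciliated cells, and that reading was withdrawn after the result was seen, because members with a high level in the controls would hide a small added share and so exclude nothing. More multiciliated cells in these dishes and a response of the genes to T3 therefore cannot be told apart here.

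Oxidative phosphorylation genes had higher values after T3 at 24 h, with a median of 0.32 log2 and 10 of 38 called. With the length and GC trend removed the median was 0.21 and 19 were called, which speaks against that trend as the whole cause. Without 24 h T3 replicate 1 it was 0.12, with 2 called and 37 of 38 positive, so most of the size of this change may come from that library. Whether T3 adds to it stays open, with 2 other T3 libraries at this time.

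The library of 6 h CHX replicate 4 stood apart from the other CHX libraries. On the oligodendrocyte lineage list it lay 0.884 log2 CPM above the highest CHX plus T3 library of the same lane. Those libraries all received T3, so this speaks against the lane as the cause only if T3 did not lower these genes. Of the oligodendrocyte lineage and neuron markers, 82.6% lay above all 3 other CHX libraries, as did 13 of 16 microglia markers and 34 of 34 motile cilia genes, while 9 of 14 vascular and meningeal markers lay below them. Of 22 astrocyte markers 14 also lay above them and 4 below, which a larger share of other cells alone would not give. Another makeup of cells in that dish is a candidate explanation, and no biological difference between the replicates is named in the labels.

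Within groups of 4 libraries, 10 of 245 measures had a library farther from the others than Dixon's 95% limit, where chance gives 12.2. For 6 h CHX replicate 4 the fourth principal component was 7.50, against −6.52 to −4.28 in the other replicates, and the mean log2 CPM of the motile cilia genes was 3.99, against 3.02 to 3.14. For 6 h CHX plus T3 replicate 3 the rank correlation of its deviations with transcript length was 0.472, against −0.318 to −0.208, and the axon guidance mean was 5.30, against 5.12 to 5.14. For 6 h control replicate 2 the immediate early mean was 4.71, against 4.91 to 4.94, and the oligodendrocyte lineage mean was 4.12, against 4.53 to 4.59. The interferon mean was 3.47 in 6 h CHX replicate 3, against 3.53 to 3.54. The motile cilia mean was 3.56 in 6 h T3 replicate 4, against 3.27 to 3.31. Klf9 was at 20.97 CPM in 24 h control replicate 2, against 20.2 to 20.3. Nrarp was at 8.24 CPM in 6 h CHX replicate 2, against 6.74 to 7.00.

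The T3 effect differed with and without CHX for 196 genes. Among the named genes the difference, T3 with CHX minus T3 without, was 0.88 log2 for Klf13, 1.51 for Nell1, 1.03 for Rec8 and 1.40 for Nrarp. It was −2.13 for Ak7, −2.31 for Cfap299, −2.05 for Dmkn, −1.99 for St18 and −1.98 for Wdr63. Among list members it was −0.37 for Atp1b2, 0.38 for Fgfr3, 0.57 for Ccna2, 0.60 for Ccnb1, 0.74 for Ccnb2 and 0.69 for Cenpf. It was 0.41 for Insig1, 0.55 for Btg2, −0.80 for Gbp2, −0.79 for Elavl4, 0.75 for Hes1 and −1.41 for Hr. Klf13, Nrarp, Ccna2, Hes1 and Hr were called without any single library. Other calls were lost, with the adjusted p given in parentheses. These were 2 without 6 h CHX replicate 1 (0.0525 to 0.0667), 3 without 6 h CHX replicate 2 (0.0564 to 0.0647), 15 without 6 h CHX replicate 4 (0.0558 to 0.173), 10 without 6 h CHX plus T3 replicate 1 (0.0533 to 0.0822), 15 without 6 h CHX plus T3 replicate 2 (0.0559 to 0.111), 15 without 6 h CHX plus T3 replicate 3 (0.0538 to 0.0763), 11 without 6 h CHX plus T3 replicate 4 (0.0508 to 0.0893) and 10 without 6 h T3 replicate 1 (0.0511 to 0.0922). They were 6 without 6 h T3 replicate 2 (0.0538 to 0.0726), 14 without 6 h T3 replicate 3 (0.0502 to 0.0799), 16 without 6 h T3 replicate 4 (0.0518 to 0.108), 12 without 6 h control replicate 1 (0.0538 to 0.0925), 16 without 6 h control replicate 2 (0.0521 to 0.114), 15 without 6 h control replicate 3 (0.0511 to 0.0863) and 1 without 6 h control replicate 4 (0.0616).

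Among lists, the median difference of T3 effects with CHX was −0.33 log2 for reactive astrocyte genes, −0.57 for microglia, −0.79 for neuron, 0.38 for cell cycle and 0.34 for Notch. With an estimated correlation the adjusted p was 0.389, 0.353, 0.335, 0.0366 and 0.00646 in that order. The motile cilia genes had a median difference of −1.13 log2 with CHX, with 0 of 34 positive and 13 called lower. Without 6 h CHX replicate 4 it was −0.86, with 1 positive and 2 called lower. With the length and GC trend removed 24 were called lower. With lane as a covariate, where the T3 effect with CHX rests on that replicate alone, the median was −1.70 and 29 were called lower. Their median after T3 with CHX was −0.42 log2, −0.15 without that library and −1.05 with lane, where 22 were called lower.

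The T3 effect differed between 24 h and 6 h for 135 genes. The difference, 24 h minus 6 h, was 1.96 log2 for Adamts16, 1.90 for Adamts17, 2.95 for Aldh1a7, 1.90 for Crabp1 and 2.70 for Aldh1a1. It was −1.34 for March4, −1.33 for Nptx1, −1.75 for St18, −1.32 for Stk32b and −1.27 for Wdr66. Among list members it was 0.42 for Acsbg1, 0.79 for Unc5b, −0.60 for Bgn, −0.74 for Lama4, 0.64 for Loxl2 and −0.77 for Nid1. It was 0.31 for Elovl5, 0.48 for Atp5b, −0.71 for Ptx3, 0.58 for Slco1a4, 1.60 for Flywch2, −0.53 for Hr and 0.62 for Acta2. Calls were lost for Bgn, Elovl5, Hr, Lama4, Atp5b, St18, Stk32b, Flywch2 and Acta2 without single libraries, and for none of the other 14. These were 5 without 24 h T3 replicate 1 (0.0771 to 0.114), 6 without 24 h T3 replicate 2 (0.0506 to 0.0995), 3 without 24 h control replicate 1 (0.052 to 0.0553), 7 without 24 h control replicate 2 (0.052 to 0.121), 1 without 24 h control replicate 3 (0.0512), 7 without 24 h control replicate 4 (0.0645 to 0.132) and 7 without 6 h T3 replicate 1 (0.0503 to 0.109). They were 7 without 6 h T3 replicate 3 (0.0612 to 0.0822), 5 without 6 h T3 replicate 4 (0.0666 to 0.121), 8 without 6 h control replicate 1 (0.0567 to 0.0916), 7 without 6 h control replicate 2 (0.0554 to 0.102), 2 without 6 h control replicate 3 (0.0602 to 0.0737) and 6 without 6 h control replicate 4 (0.0668 to 0.0878).

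Among lists, the median difference between times was −0.33 log2 for reactive astrocyte genes, −0.37 for microglia, −0.65 for oligodendrocyte lineage, −0.68 for neuron, −0.16 for immediate early, 0.28 for ribosomal protein and 0.43 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.688 for ribosomal proteins and 0.637 for each of the others. The means of reactive astrocyte, microglia, oligodendrocyte lineage and neuron genes were highest at 24 h in control replicates 2 and 4. This lowers the 24 h T3 values of these lists. Without 24 h T3 replicate 1 the ribosomal protein list was not called at the preset correlation (camera adjusted p = 0.478) and its median was 0.01, while that of oxidative phosphorylation was 0.21. With the length and GC trend removed these medians were 0.11 and 0.28. The motile cilia genes had a median difference between times of −0.735 log2, with 1 called lower, and of −0.72 without 24 h T3 replicate 1, where that call was lost. With the length and GC trend removed 5 were called lower, and 10 with lane as a covariate, where the 24 h T3 effect rests on T3 replicates 1 and 2.

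Outside the gene counts, reads without a feature made up 5.07 ± 0.516% of the counts in the 6 h CHX plus T3 libraries, each above all 6 h CHX libraries, with 4.48 ± 0.170% (SD, n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.0857). Ambiguous reads made up 1.70 ± 0.00591% in the 6 h CHX libraries, each above all 6 h controls, with 1.48 ± 0.0528% (SD, n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.0857). With the same p and n, alignments that were not unique were fewer with CHX, at 32.6 ± 0.285% against 39.4 ± 1.99% in the controls, and ambiguous reads fewer with CHX plus T3, at 1.65 ± 0.0173% against 1.70 ± 0.00591% with CHX (SD). The smallest p these groups allow is 0.0286.

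Other splits of the same libraries were fitted for each count. For T3 at 6 h, 1 of 35 splits, the real one, gave as many genes, 606 against at most 1 in the others. At 24 h, 1 of 35 splits was as large, with 1140 genes, and the highest of the others reached 49.5% of that count. That split set control replicates 1, 2 and 4 against control replicate 3 and all T3 libraries, so it largely mirrors the real one. Among splits with T3 libraries on both sides the highest count was 147. With CHX the count was 208 against 0 and for CHX itself 10862 against 0, each with 1 of 35 splits as large. For the difference with CHX 1 of 100 splits was as large, 196 against 59, and for that between times 1 of 100, 135 against 78. For the main comparisons chance is an unlikely cause, at 1 of 35 splits. For the differences of T3 effects the splits shuffled T3 and control libraries within each arm. They stand for no T3 effect at all and not for equal T3 effects, so they cannot decide whether the effects differ. Of the 78 genes in the highest split between times, 75 were shared with those called for T3 at 6 h. The overlaps of T3 genes at 6 h were 124 with CHX against 0, and 277 at 24 h against 1, with 1 of 35 splits as large. Since the other splits at 6 h called at most 1 gene, their overlaps could not be larger, and this decides nothing about the overlaps. It had first been read as excluding chance for them, and that reading was withdrawn after the result was seen.

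For counts of lists called by camera at the preset correlation chance cannot be excluded. As many lists were called, the real split included, in 9 of 35 splits for T3 at 6 h (8 lists, at most 11 in the others), 13 of 35 at 24 h (9, at most 13), 3 of 35 with CHX (13, at most 15) and 12 of 35 for CHX (11, at most 14). This was so in 66 of 100 splits for the difference with CHX (5 lists, at most 12) and in 40 of 100 for that between times (7, at most 12).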

How the results depend on the processing

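The fits with the length and GC trend removed, and without 24 h T3 replicate 1 and 6 h CHX replicate 4, were chosen only after the results were seen. Unless a reason is given, the cause was not tested. Of 303 calls of named genes, 302 were kept with DESeq2, 300 with RLE factors, 295 without the low-count filter, 300 with the length and GC trend removed and 285 with lane as a covariate. The fit of only the groups compared kept 253 and that without both libraries 277. Over all fits without a single library 2223 of 2686 were kept, and no call reversed.

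Genes called for T3 at 6 h numbered 1226 with the length and GC trend removed, 1191 without both libraries, and 349 to 676 without single libraries, against 606. For T3 at 24 h they numbered 1795 with the trend removed, 401 in a fit of only those groups and 810 to 1486 without single libraries, against 1140. With CHX the numbers were 660 with lane as a covariate, 388 with the trend removed, 343 with DESeq2, 407 with only those groups and 138 to 252 without single libraries, against 208. CHX itself gave 10426 to 10573 without single libraries, against 10862. By construction, with lane as a covariate the comparisons within CHX rest on 6 h CHX replicate 4, the only CHX library that shares a lane with CHX plus T3.

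The difference of T3 effects with CHX gave 295 genes without the low-count filter, 966 with lane, 693 with the trend removed, 514 with DESeq2, 497 with only those groups and 30 to 334 without single libraries, against 196. That between times gave 521, 410, 365 and 62 with lane, the trend removed, DESeq2 and only those groups, and 69 to 350 without single libraries, against 135. The overlap at 6 h with CHX was 187 with the trend removed and 104 to 125 without single libraries, against 124. That of 6 h and 24 h was 508 with the trend removed, 435 without both libraries, 166 in fits of only the groups compared and 215 to 292 without single libraries, against 277.

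Lists called by camera numbered 1 with an estimated correlation and 3 by fry for T3 at 6 h, against 8, and 1 with an estimated correlation at 24 h, against 9. They numbered 2 with an estimated correlation and 5 by fry with CHX, against 13, and 0 with an estimated correlation for CHX, against 11. For the difference with CHX they numbered 9 with lane and 2 with an estimated correlation, against 5. For that between times they numbered 4 with lane, 0 with an estimated correlation and 0 by fry, against 7. Without single libraries the ranges were 7 to 8, 7 to 12, 12 to 14, 10 to 11, 5 to 7 and 4 to 7 in the same order.

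Replicate numbers gave no clear pairing of the libraries, though pairs with unequal numbers were not compared, so a shared culture is not excluded. Deviations from group means of libraries with the same number correlated at −0.0632 to 0.211 in 24 pairs at 6 h, 4 of them over 0.1, and at −0.0882 to 0.0616 in 3 pairs at 24 h. With letters in the descriptions in place of numbers the 24 h values were −0.0225 to 0.0323. With the number as a replicate block the difference of T3 effects with CHX gave 381 genes, and the other counts of genes stayed within 1.5 times. The block kept 286 of 303 named calls, and the letters kept 81 of 98.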

Other observations

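The test of the genes lowered at 6 h was chosen only after the result was seen, as were the genes of multiciliated cells named here.

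For regulators of multiciliated cell formation, picked by hand, levels in the 6 h and 24 h controls are given without a test of these genes, and these controls also differ in sequencing lane. Foxj1, a transcription factor gene of motile cilia, was at 428 ± 56.4 CPM in the 6 h controls and 938 ± 105 CPM in the 24 h controls (SD, n = 4 each). Mcidas, which starts the multiciliated programme, was at 2.78 ± 0.29 and 27.8 ± 7.48 CPM. Deup1, a gene of centriole formation, was at 8.24 ± 1.37 and 42.8 ± 13.9 CPM, and Myb at 6.46 ± 1.05 and 61.8 ± 10.9 CPM. The mean log2 CPM of 34 motile cilia genes was 1.60 higher in the 24 h controls (exact two-sided permutation p = 0.0286, the smallest these groups allow). The 24 h T3 libraries had a median of −0.00 log2 for these genes against their own controls, with Foxj1 at 963 ± 81.8 CPM and Deup1 at 40.8 ± 8.33 CPM (SD, n = 3).

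With 6 h of CHX, Gmnc, another regulator of this programme, was at 35.3 ± 2.54 CPM against 15.7 ± 0.736 CPM in the 6 h controls, and Ccno at 31 ± 7.99 against 14.8 ± 1.22 CPM (SD, n = 4 each). The motile cilia genes had a median of 0.62 log2 with CHX, and of 0.34 without 6 h CHX replicate 4.

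A hypothesis is that the lowering of genes by T3 at 6 h needs new protein, while part of the raising does not. The 186 genes lowered at 6 h had a median of 0.0104 log2 with CHX (quartiles −0.05 to 0.10) and of −0.21 at 24 h (quartiles −0.36 to −0.10). At an unadjusted p under 0.05, 7 of them were lower and 25 higher with CHX, against 103 lower and 2 higher at 24 h. These values are consistent with the hypothesis, though CHX changed 67.5% of all tested genes, so other routes may also give them.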
